A study of Homo sapiens with 6 samples.

How the data were processed

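HEK293T cells were transfected and kept for 48 h with a photocaged serine (0.1 mM), in which a dimethoxynitrobenzyl group blocks the side chain. Per the labels' protocols they were then washed, exposed or not to light of 365 nm for 3 min, and returned to medium for 4 h or 8 h. Per the labels, 500000 transfected cells were sorted for each sample, total RNA was taken with TRIzol, mRNA was enriched and libraries were sequenced on the DNBseq platform. The 6 libraries fall into 3 groups of 2 by their titles, treatment and time: caged 0 h, uncaged 4 h and uncaged 8 h.

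The authors deposited estimated counts (expected counts, not normalised) for each feature. Per the submitters' processing notes these came from Salmon 1.1.0 with GRCh38, and R 3.6.1 and DESeq2 were also used; the DESeq2 version and the transcript annotation are not given in the sources used here. The table holds 60184 features, of which 5 are plasmid sequences and 41692 carry a gene symbol. The plasmid sequences took 11.5% to 15.5% of each library and were left out of library sizes and tests, then reported with the same fit. Salmon divides reads that match several transcripts, so an estimate that is not whole within 0.01 marks a feature that shares reads with another: between 20.3% and 21.7% of all gene features in each library. Features at 0 count as whole in these shares. Among tested features without a called change of over 4-fold, 66.5% had such an estimate in some library and 51.5% in at least 4. Paralogs, pseudogenes, overlapping genes and antisense genes are uncertain because of shared reads, and the strand setting is not given in the sources used here.

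Totals ran from 17490010 to 20025955 estimated counts a library. A count of 0 allows up to 3 counts, which is 0.164 to 0.210 CPM in a single library; such floors cover counting error only. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom 4.03, 3.57 and 4.21), so no library was counted as a copy of another. The common biological coefficient of variation was 6.34%.

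Estimated counts were rounded to whole numbers. Features were filtered with filterByExpr (minimum count 10, minimum total 15), normalised by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test with legacy=TRUE over all 6 libraries, without covariates. The SE of a log2 fold change was its size divided by the square root of F. Of the features, 17449 were tested, 13968 of them protein coding, with 3 residual and 5.43 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg over the features of one comparison with a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, for lists of at least 5 tested members, and adjusted over the lists of one comparison. With an estimated correlation none of the 14, 21 and 20 lists that passed at 4 h, at 8 h and between them held its call; the lowest adjusted p was 0.269, 0.255 and 0.344.

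Before the data were examined, 52 gene lists, the design and a rule for naming genes were fixed. The rule takes TET2, TET1, TET3, DNMT1, DNMT3A, DNMT3B and TDG always. It takes the 10 largest called folds in each direction among features with a symbol, at least 1 CPM in the higher group and no overlap between groups. It takes the 4 members of smallest p in the list's direction from each list past camera, and at most 4 called members from each other list. XIST and Y-linked genes were left out, and some other genes the rule named are not reported here. The rule named 145, 199 and 122 genes in the 3 comparisons. The text gives a part of these, and which ones was chosen after their values were seen, so the named genes are examples and the counts carry each comparison. ZNF503 was named by the rule in the 4 h comparison only, and its step from 4 h to 8 h is given as well.

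The alternatives fixed in advance were RLE size factors, upper-quartile factors and library totals for scaling; DESeq2 1.42.0, limma-voom and glmTreat against a 1.2-fold change as tests; no filter, or at least 1 CPM in 2 libraries; a replicate block; unrounded counts; legacy=FALSE; robust=TRUE; the 4 compared libraries alone; each library left out in turn; and for lists fry, ranks and an estimated correlation. Chosen after the data were seen were inclusion of the plasmid sequences, length and GC offsets (98.9% of tested features had both values), cyclic loess offsets against abundance, and a fit of features with whole estimates only. A group left with 1 library was assumed to vary like the others.

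The procedure was tested on simulated counts with 200 changed features and a further list of features raised 1.5-fold. In the 4 h comparison the edgeR fit recovered 12%, 52%, 60% and 100% of changes of 1.25-, 1.5-, 2- and 4-fold, in the 8 h comparison 24%, 48%, 86% and 94%, and in the step between them 36%, 50%, 72% and 98%. Unchanged features made up 13.0%, 9.49% and 12.0% of all calls, those of the raised list included, which is above the nominal rate. The simulated comparisons gave 154, 158 and 166 calls, against 1696, 4907 and 570 in the data. The adjusted threshold depends on how many features change, so these rates do not carry over directly to the data. Of 24 false calls in 5 draws with no change in the 4 h comparison, 22 had a dispersion over 5 times the trend and 23 had estimates that were not whole, and draws from the dispersion trend gave 0.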

Results

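HEK293T is a human embryonic kidney line that carries the SV40 large T antigen. The cells were co-transfected with a pair of plasmids that serve to make a light-activatable human TET2, an enzyme that oxidises 5-methylcytosine in DNA. In the caged form a serine is blocked by a photolabile nitrobenzyl group, which ultraviolet light removes. Messenger RNA of sorted transfected cells was sequenced in 3 groups of 2 libraries: before light (caged 0 h), 4 h after light (uncaged 4 h) and 8 h after light (uncaged 8 h). The question of the series is how mRNA levels stood before deprotection and at 4 h and 8 h after TET2 was activated. The total estimated counts were 20025955 and 19742156 in the caged libraries, 17961652 and 17744751 at 4 h and 17720964 and 17490010 at 8 h. Every fold change below is a log2 fold change ± SE from 2 libraries a group, and levels are mean ± SD (n = 2) in normalised counts (CPM). Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. No group received light without the enzyme, so light, washing, fresh medium, elapsed time and the uncaged enzyme cannot be separated in either comparison with caged cells.

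Transcript from the plasmids was more abundant after light. The mCherry sequence rose by 0.86 ± 0.049 at 4 h and by 0.62 ± 0.049 at 8 h, and it was lower at 8 h than at 4 h (-0.24 ± 0.049, adjusted p = 0.0431). The 2 plasmid segments named for TET2 rose as well: the amber segment by 0.55 ± 0.041 and 0.73 ± 0.041, and the start segment by 0.51 ± 0.022 and 0.57 ± 0.022. Plasmid sequences took 11.8% and 11.5% of the caged libraries, 15.1% and 14.96% at 4 h and 15.5% and 14.8% at 8 h. The level assigned to the TET2 gene (chromosome 4, 105145875 to 105279816 of GRCh38, with 1-based coordinates as in the GENCODE 29 annotation) rose from 3277 ± 24.3 to 4071 ± 34.4 CPM at 4 h, by 0.31 ± 0.033 (adjusted p = 0.00247), and by 0.47 ± 0.033 at 8 h (adjusted p = 0.000221). Its step from 4 h to 8 h was 0.16 ± 0.033 (adjusted p = 0.0451) and turned to -0.025 under cyclic loess offsets, and it lost the call in each of the 6 fits that left out 1 library (adjusted p = 0.0648 to 0.174). Neither rise over caged cells passed under cyclic loess offsets, where TET2 stood at 0.0997 (adjusted p = 0.110) at 4 h and 0.0744 (adjusted p = 0.139) at 8 h. Its estimates were not whole numbers in all 6 libraries, and reads of the gene cannot be separated from those of the plasmid copy, so none of these values measures the chromosomal gene alone.

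**Figure D1:**
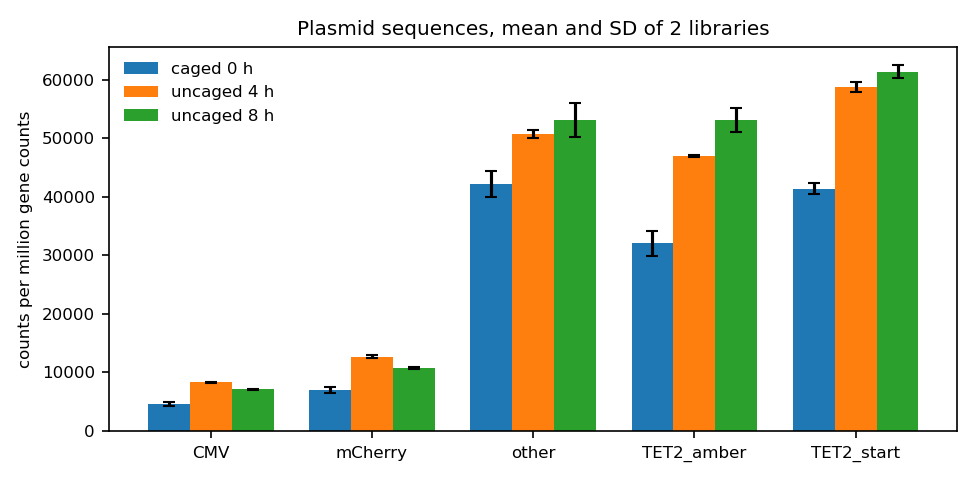
Level of each plasmid sequence in CPM of the gene counts, with bars for the mean and error bars for the SD of the 2 libraries in each group. The bars of all 5 sequences are higher at 4 h and 8 h than in caged cells, and the mCherry bar is lower at 8 h than at 4 h.

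In the first 4 h after light, the mRNA of TET1 fell while those of AMOTL2, HEY1, LIF and MYC rose. TET1, the paralogue of the transfected enzyme (chromosome 10, 68560656 to 68694482), went from 40.5 ± 1.35 to 28.1 ± 0.922 CPM, a change of -0.53 ± 0.093 (adjusted p = 0.0130). AMOTL2, a regulator of YAP (chromosome 3, 134355874 to 134375479), rose by 1.40 ± 0.056 (adjusted p = 6.22e-05), the Notch target HEY1 by 1.06 ± 0.064, the cytokine gene LIF by 1.08 ± 0.088 and MYC by 1.09 ± 0.091 (adjusted p = 0.00109). Of 17449 features tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1074 were higher and 622 lower at 4 h than in caged cells. The median called change was 1.35-fold, and 119 of the higher and 91 of the lower features changed over 2-fold.

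Of the 7 enzyme genes of DNA methylation and demethylation fixed in advance, TET2 and TET1 were called at 4 h. The TET2 call does not show a change of the chromosomal gene, because its reads cannot be separated from those of the plasmid copy. TET3 stood at 0.19 ± 0.10, DNMT1 at 0.15 ± 0.055, DNMT3A at -0.13 ± 0.068, DNMT3B at -0.16 ± 0.090 and the thymine glycosylase gene TDG at 0.093 ± 0.064, none past the test. Of the DNA methylation readers and writers, 4 higher and 2 lower of 26 (6 and 3 adjusted over the list alone) were called, among them the methyl-CpG reader MBD1 (0.35 ± 0.059).

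Immediate-early genes rose more often than they fell: 17 of 47 tested members were higher and 4 lower (19 and 7 adjusted over the list alone). Immediate-early genes had a median log2 fold change of 0.24 (camera adjusted p = 0.00386, adjusted p = 0.269 with an estimated correlation). PPP1R15A, which directs dephosphorylation of eIF2, rose by 0.49 ± 0.062, JUN by 0.38 ± 0.042 and SPRED2 by 0.63 ± 0.075. In the ATF4 integrated stress response list, 9 of 48 tested members were higher and 2 lower (13 and 2 adjusted over the list alone). Integrated stress response genes had a median log2 fold change of 0.10 (camera adjusted p = 0.000329, adjusted p = 0.269 with an estimated correlation). Its call was lost under cyclic loess offsets (adjusted p = 0.534, median -0.015). ATF5 rose by 1.21 ± 0.13, the arginine transporter gene SLC7A1 by 0.57 ± 0.056 and ATF4 itself by 0.42 ± 0.042. TGF-beta and BMP targets included SMAD6 (0.92 ± 0.12) and ID1 (0.73 ± 0.12): 7 of 25 tested members were higher and 2 lower (8 and 3 adjusted over the list alone). TGF-beta and BMP targets had a median log2 fold change of 0.17 (camera adjusted p = 0.0219, adjusted p = 0.339 with an estimated correlation). Their median was 0.27 with length and GC offsets.

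Targets of p53 moved in one direction at 4 h: 13 of 32 tested members were higher and 0 lower (18 and 0 adjusted over the list alone). Activity of p53 itself was not measured, so here and below the list's name does not show that p53 caused the changes. Targets of p53 had a median log2 fold change of 0.22 (camera adjusted p = 9.63e-09, adjusted p = 0.428 with an estimated correlation). The death receptor gene TNFRSF10B rose by 0.56 ± 0.052 (adjusted p = 0.00181), the damage-recognition gene XPC by 0.33 ± 0.049 and the nuclease gene AEN by 0.30 ± 0.041. For nucleotide excision repair and UV damage, 7 of 26 tested members were higher and 0 lower (8 and 0 adjusted over the list alone). These repair genes had a median log2 fold change of 0.10 (camera adjusted p = 0.000822, adjusted p = 0.269 with an estimated correlation). DDB2, part of the UV-damage sensor, rose by 0.30 ± 0.055, and DDB2 and XPC belong to this list and to the p53 targets. The list of S phase and the G1/S step held MCM5 of the replicative helicase at 0.38 ± 0.048 and the uracil glycosylase gene UNG at 0.51 ± 0.054: 16 of 51 tested members were higher and 0 lower (21 and 0 adjusted over the list alone). S-phase and G1/S genes had a median log2 fold change of 0.14 (camera adjusted p = 7.76e-08, adjusted p = 0.269 with an estimated correlation). Under cyclic loess offsets the calls of S-phase and G1/S genes (adjusted p = 0.137, median 0.022) and repair genes (adjusted p = 0.0558, median 0.079) were lost, and the p53 targets kept theirs (adjusted p = 0.00287, median 0.11).

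Lists of RNA and chromatin machinery also passed at 4 h. For splicing factors, 17 of 37 tested members were higher and 0 lower (26 and 3 adjusted over the list alone). Splicing factors had a median log2 fold change of 0.19 (camera adjusted p = 2.61e-09, adjusted p = 0.50 with an estimated correlation), with SRSF6 at 0.70 ± 0.049 (adjusted p = 0.000707) and SRSF5 at 0.61 ± 0.061. In Myc targets and ribosome biogenesis, 16 of 46 tested members were higher and 0 lower (22 and 2 adjusted over the list alone). Myc and ribosome biogenesis genes had a median log2 fold change of 0.15 (camera adjusted p = 3.33e-07, adjusted p = 0.269 with an estimated correlation), and the ribosome assembly gene GRWD1 rose by 0.51 ± 0.063. Among histone and chromatin modifiers, 16 of 54 tested members were higher and 1 lower (19 and 4 adjusted over the list alone). Histone and chromatin modifiers had a median log2 fold change of 0.12 (camera adjusted p = 0.000329, adjusted p = 0.339 with an estimated correlation). The acetyltransferase genes EP300 and CREBBP rose by 0.71 ± 0.070 and 0.67 ± 0.070, and the deacetylase gene SIRT1 by 0.51 ± 0.068. Core polyadenylated histone genes included H2AC6 (1.1 ± 0.14) and H4C8 (0.93 ± 0.13): 7 of 12 tested members were higher and 0 lower (7 and 0 adjusted over the list alone). Core polyadenylated histone genes had a median log2 fold change of 0.55 (camera adjusted p = 0.000822, adjusted p = 0.339 with an estimated correlation). The proteasome list passed with few called members, of which PSMC3 rose by 0.37 ± 0.053. There 2 of 36 tested members were higher and 0 lower (2 and 0 adjusted over the list alone). Proteasome genes had a median log2 fold change of 0.078 (camera adjusted p = 0.00817, adjusted p = 0.50 with an estimated correlation). With cyclic loess offsets the calls of splicing factors (adjusted p = 0.0969, median 0.056), histone and chromatin modifiers (adjusted p = 0.0549, median 0.057) and the proteasome (adjusted p = 0.867, median -0.016) were lost. Myc and ribosome biogenesis genes kept theirs (adjusted p = 0.0403, median 0.087).

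Lists that stood lower at 4 h were fewer. Of the mitochondrially encoded genes, 1 of 13 tested members were higher and 5 lower (1 and 8 adjusted over the list alone). Mitochondrially encoded genes had a median log2 fold change of -0.20 (camera adjusted p = 0.000329, adjusted p = 0.50 with an estimated correlation), with MT-ND6, the light-strand subunit of complex I, at -0.78 ± 0.11 and MT-ND4 at -0.40 ± 0.064. In the heat shock response, 1 of 27 tested members were higher and 5 lower (1 and 7 adjusted over the list alone). Heat shock genes had a median log2 fold change of -0.10 (camera adjusted p = 0.0355, adjusted p = 0.50 with an estimated correlation). HSPA1B fell by 0.71 ± 0.079 and HSPB1 by 0.34 ± 0.073, and HSPA1B shares near-identical sequence with HSPA1A. Among Polycomb-target developmental regulators, 5 of 52 tested members were higher and 4 lower (5 and 8 adjusted over the list alone). Polycomb-target developmental regulators had a median log2 fold change of -0.15 (camera adjusted p = 0.0300, adjusted p = 0.50 with an estimated correlation), with NKX6-1 at -0.70 ± 0.15 and ISL1 at -0.55 ± 0.13. Cyclic loess offsets ended the call of the Polycomb targets (adjusted p = 0.209, median -0.11) and lowered the medians of heat shock genes (adjusted p = 8.52e-07, median -0.23) and mitochondrially encoded genes (adjusted p = 2.05e-13, median -0.43). Single genes of other lists also moved: HOXC11 stood at -0.67 ± 0.10, IFIT5 at -0.69 ± 0.14, PER2 at 0.94 ± 0.095, and the nuclear RNAs MALAT1 at -1.05 ± 0.14 and KCNQ1OT1 at -1.26 ± 0.18.

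Scarce features were among the largest called folds at 4 h. INMT-MINDY4 had 0 counts in both caged libraries and was at least 28.8-fold higher against a floor of 3 counts over the group. The pseudogene RHEBP1 had 0 counts at 4 h and was at least 35.9-fold lower, and the antisense RNA RCC2-AS1, also at 0, at least 33.9-fold lower. Other large called folds, given as examples and not in order, were those of H4C15 (4.07 ± 0.81), ZCCHC12 (2.15 ± 0.13), EGR4 (2.62 ± 0.58) and NKX2-3 (-2.68 ± 0.41). The estimates of INMT-MINDY4, RHEBP1, RCC2-AS1, H4C15 and ZCCHC12 were not whole in 3, 3, 4, 6 and 6 libraries, so reads shared with other transcripts leave them uncertain. Of the 48 called genes named for this comparison, 26 kept their call with each library left out in turn, and TET1 lost it without any one of the 4 libraries compared. The list calls of heat shock genes were lost without caged replicate 2 or 4 h replicate 1, of Polycomb targets without 4 h replicate 1, and of the proteasome without caged replicate 1 or 4 h replicate 1. Camera on ranks ended the calls of heat shock genes and of TGF-beta and BMP targets. AEN, DDB2 and ISL1 lost their calls under cyclic loess offsets, and MALAT1, H4C15, INMT-MINDY4 and RHEBP1 with robust=TRUE. Without a low-count filter NKX6-1, ISL1, DDB2, H4C15, INMT-MINDY4, RHEBP1 and EGR4 lost theirs. DESeq2 also ended the call of ISL1 and limma-voom that of H4C15. With a replicate block NKX6-1, ISL1, INMT-MINDY4, RHEBP1, IFIT5 and EGR4 lost their calls. Under glmTreat TET1, MBD1, JUN, PPP1R15A, XPC, AEN, MCM5, SIRT1, ID1, MT-ND4, HSPB1, NKX6-1, ISL1, DDB2, PSMC3, H4C15, INMT-MINDY4, RHEBP1, IFIT5 and EGR4 were without a call. Without one of those 4 libraries the fit called 165 to 420 features higher and 61 to 153 lower, and with library totals alone 44.7% of calls were higher in place of 63.3%.

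At 8 h more features were called than at 4 h, although 3 lists that passed at 4 h did not pass here. TET1 stood at 24.0 ± 3.06 CPM, -0.76 ± 0.095 against caged cells (adjusted p = 0.00148), although its step from 4 h to 8 h did not pass the test (-0.23 ± 0.10, adjusted p = 0.209). Of 32 p53 targets 25 were called higher and of 37 splicing factors 27, while 71 of 254 solute carriers were called lower. The adjusted p of these lists with an estimated correlation was 0.330, 0.377 and 0.279. AMOTL2 stood at 1.40 ± 0.056, LIF at 1.39 ± 0.088 and the receptor gene PDGFRB at 1.89 ± 0.16. Of the 17449 features, 2602 were higher and 2305 lower, with a median called change of 1.35-fold, and 340 and 237 of them changed over 2-fold. Of those 3 lists, heat shock genes held 8 higher and 4 lower of 27 (9 and 5 adjusted over the list alone), with a median of -0.057 and camera pointing up (adjusted p = 0.922). TGF-beta and BMP targets held 7 higher and 4 lower of 25 (10 and 4 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.0611, fry adjusted p = 0.00824). Mitochondrially encoded genes held 2 higher and 2 lower of 13 (2 and 2 adjusted over the list alone). Their median was -0.079 (camera adjusted p = 0.521). With length and GC offsets the medians of heat shock genes, TGF-beta and BMP targets and mitochondrially encoded genes were -0.057, 0.370 and -0.231. Under cyclic loess offsets they were -0.187, 0.249 and -0.420.

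Genes of the methylation enzymes moved in both directions at 8 h. DNMT3B (-0.46 ± 0.092) and DNMT3A (-0.30 ± 0.069), the de novo methyltransferase genes, were lower, whereas DNMT1 (0.20 ± 0.055) and TDG (0.28 ± 0.064) were higher and TET3 was not past the test (0.14 ± 0.10), although with length and GC offsets it was (0.252, adjusted p = 0.0459). DNMT1 and DNMT3A each lost their call without any one of the 4 libraries compared, DNMT3B without caged replicate 1, and TDG without caged replicate 1 or 8 h replicate 2. DNMT1 and TDG also lost it with library totals alone and under cyclic loess offsets, DNMT1 without a low-count filter, and DNMT3A with DESeq2 and with length and GC offsets. The methyl-CpG reader MBD1 rose by 0.48 ± 0.059. For DNA methylation readers and writers the counts were 6 higher and 7 lower of 26 (7 and 9 adjusted over the list alone).

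Of the p53 targets, 25 of 32 tested members were higher and 0 lower (25 and 0 adjusted over the list alone). Targets of p53 had a median log2 fold change of 0.40 (camera adjusted p = 2.07e-13, adjusted p = 0.330 with an estimated correlation). TNFRSF10B rose by 0.76 ± 0.052 (adjusted p = 0.000217), DDB2 by 0.56 ± 0.055, TRIAP1 by 0.53 ± 0.051 and XPC by 0.48 ± 0.049, and the cell-cycle inhibitor gene CDKN1A by 0.36 ± 0.056. In nucleotide excision repair and UV damage, 14 of 26 tested members were higher and 0 lower (15 and 2 adjusted over the list alone). These repair genes had a median log2 fold change of 0.20 (camera adjusted p = 0.000160, adjusted p = 0.279 with an estimated correlation), with the transcription-coupled repair gene ERCC6 at 0.83 ± 0.10. Of the immediate-early genes, 15 of 47 tested members were higher and 7 lower (16 and 8 adjusted over the list alone). Immediate-early genes had a median log2 fold change of 0.20 (camera adjusted p = 0.0294, adjusted p = 0.330 with an estimated correlation); FOSL1 rose by 1.17 ± 0.082, PPP1R15A by 0.85 ± 0.062 and ATF3 by 0.66 ± 0.057. In the ATF4 integrated stress response, 14 of 48 tested members were higher and 6 lower (16 and 7 adjusted over the list alone). Integrated stress response genes had a median log2 fold change of 0.084 (camera adjusted p = 0.0317, adjusted p = 0.377 with an estimated correlation), with ATF5 at 1.43 ± 0.13. Its median turned negative with library totals alone, and its call was lost under cyclic loess offsets (adjusted p = 0.488, median -0.063). The p53 targets kept theirs with those offsets (adjusted p = 3.85e-07, median 0.26), although CDKN1A did not. The calls of the immediate-early and stress response lists were also lost without caged replicate 1, without 8 h replicate 2 and with camera on ranks.

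**Figure D2:**
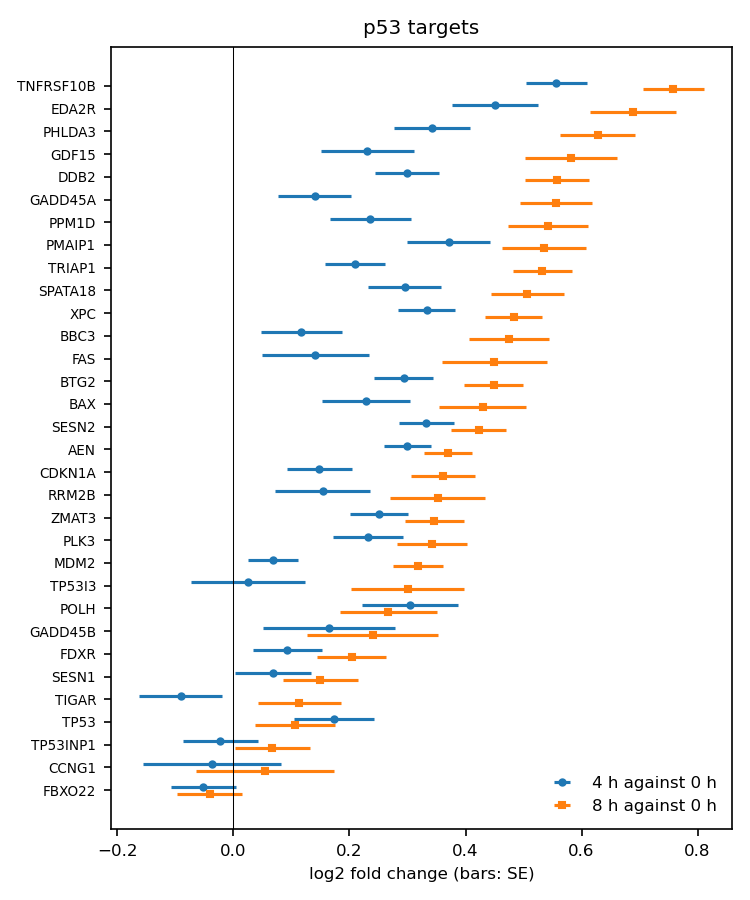
Log2 fold change of the 32 tested p53 targets at 4 h and at 8 h against caged cells, with points for the fitted value and bars for its SE. At 8 h, 25 of the 32 were called higher and 0 lower.

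Lists of RNA and protein machinery passed at 8 h. Of the splicing factors, 27 of 37 tested members were higher and 0 lower (28 and 0 adjusted over the list alone). Splicing factors had a median log2 fold change of 0.41 (camera adjusted p = 1.57e-14, adjusted p = 0.377 with an estimated correlation), with SRSF6 at 0.66 ± 0.049, SON at 0.65 ± 0.051 and SRSF2 at 0.55 ± 0.043. In Myc targets and ribosome biogenesis, 28 of 46 tested members were higher and 1 lower (34 and 1 adjusted over the list alone). Myc and ribosome biogenesis genes had a median log2 fold change of 0.24 (camera adjusted p = 7.20e-10, adjusted p = 0.255 with an estimated correlation), among them GRWD1 (0.61 ± 0.063) and NIP7 (0.58 ± 0.063). In the proteasome, 22 of 36 tested members were higher and 1 lower (27 and 1 adjusted over the list alone). Proteasome genes had a median log2 fold change of 0.25 (camera adjusted p = 6.29e-09, adjusted p = 0.279 with an estimated correlation), with PSMC3 at 0.61 ± 0.053 and PSMD12 at 0.48 ± 0.071. Of the cytosolic ribosomal proteins, 33 of 80 tested members were higher and 0 lower (47 and 0 adjusted over the list alone). Cytosolic ribosomal proteins had a median log2 fold change of 0.14 (camera adjusted p = 4.68e-10, adjusted p = 0.478 with an estimated correlation), with RPL6 at 0.37 ± 0.040 and RPL24 at 0.32 ± 0.046, but under cyclic loess offsets the list was called lower (adjusted p = 5.98e-10). Of the mitochondrial ribosomal proteins, 24 of 78 tested members were higher and 4 lower (26 and 4 adjusted over the list alone). Mitochondrial ribosomal proteins had a median log2 fold change of 0.15 (camera adjusted p = 0.000160, adjusted p = 0.461 with an estimated correlation), with MRPL51 at 0.47 ± 0.067. Nuclear-encoded oxidative phosphorylation included NDUFA9 at 0.45 ± 0.069, and its median turned negative with library totals alone: 16 of 75 tested members were higher and 0 lower (14 and 0 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.082 (camera adjusted p = 0.00105, adjusted p = 0.580 with an estimated correlation). That call was lost with length and GC offsets (adjusted p = 0.238, median 0.038) and cyclic loess offsets (adjusted p = 0.400, median 0.033). Under cyclic loess offsets the splicing (adjusted p = 0.000394, median 0.19), Myc (adjusted p = 0.00321, median 0.10) and proteasome (adjusted p = 0.00541, median 0.10) lists kept their calls with smaller medians, and RPL6 and RPL24 lost theirs.

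Cell-cycle and chromatin lists passed too. For S phase and G1/S, 22 of 51 tested members were higher and 1 lower (26 and 1 adjusted over the list alone). S-phase and G1/S genes had a median log2 fold change of 0.14 (camera adjusted p = 1.81e-05, adjusted p = 0.255 with an estimated correlation), with E2F8 at 0.68 ± 0.075 and GINS3 at 0.60 ± 0.069. For G2/M genes, 21 of 57 tested members were higher and 6 lower (27 and 6 adjusted over the list alone). G2/M genes had a median log2 fold change of 0.17 (camera adjusted p = 0.00206, adjusted p = 0.398 with an estimated correlation), with the kinesin gene KIF4A at 0.62 ± 0.075 and PRC1 at 0.48 ± 0.067. Of the core polyadenylated histone genes, 7 of 12 tested members were higher and 0 lower (8 and 0 adjusted over the list alone). Core polyadenylated histone genes had a median log2 fold change of 0.88 (camera adjusted p = 2.18e-05, adjusted p = 0.279 with an estimated correlation), with H4C8 at 1.39 ± 0.13 and H2AC6 at 1.28 ± 0.14. Histone and chromatin modifiers held EP300 at 0.78 ± 0.070: 19 of 54 tested members were higher and 5 lower (22 and 9 adjusted over the list alone). Histone and chromatin modifiers had a median log2 fold change of 0.11 (camera adjusted p = 0.0392, adjusted p = 0.478 with an estimated correlation). Among zinc finger ZNF genes, 113 of 451 tested members were higher and 48 lower (125 and 57 adjusted over the list alone). ZNF genes had a median log2 fold change of 0.11 (camera adjusted p = 0.0178, adjusted p = 0.478 with an estimated correlation). Members included ZNF776 (1.30 ± 0.085) and ZNF317 (0.88 ± 0.053). The list of nuclear-retained noncoding RNAs, as fixed in advance, held NORAD (0.44 ± 0.064) and TUG1 (0.35 ± 0.052). There 8 of 24 tested members were higher and 2 lower (10 and 2 adjusted over the list alone). Nuclear-retained noncoding RNAs had a median log2 fold change of 0.16 (camera adjusted p = 0.0392, adjusted p = 0.377 with an estimated correlation). Cyclic loess offsets ended the calls of S-phase and G1/S genes (adjusted p = 0.932, median -0.014), G2/M genes (adjusted p = 0.0609, median 0.050), chromatin modifiers (adjusted p = 0.681, median 0.021) and nuclear-retained RNAs (adjusted p = 0.697, median 0.064). Length and GC offsets also ended that of nuclear-retained RNAs (adjusted p = 0.0948, median 0.14). The calls of ZNF genes and nuclear-retained RNAs were lost without caged replicate 1 or 8 h replicate 2, and that of chromatin modifiers without caged replicate 2, without 8 h replicate 2 and with camera on ranks.

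At 8 h, 5 lists stood lower. Of the solute carriers, 13 of 254 tested members were higher and 71 lower (15 and 73 adjusted over the list alone). Solute carriers had a median log2 fold change of -0.17 (camera adjusted p = 0.000940, adjusted p = 0.279 with an estimated correlation), with the glucose transporter gene SLC2A12 at -1.66 ± 0.21 and SLC25A29 at -0.84 ± 0.095. Of the very long neuronal genes, 0 of 24 tested members were higher and 7 lower (0 and 7 adjusted over the list alone). Very long neuronal genes had a median log2 fold change of -0.21 (camera adjusted p = 0.00262, adjusted p = 0.430 with an estimated correlation), with MAGI2 at -1.02 ± 0.17 and CNTNAP2 at -0.64 ± 0.10. Of the HOX genes, 0 of 37 tested members were higher and 10 lower (0 and 10 adjusted over the list alone). HOX genes had a median log2 fold change of -0.19 (camera adjusted p = 0.00682, adjusted p = 0.478 with an estimated correlation), with HOXC6 at -0.46 ± 0.073. In the Polycomb-target developmental regulators, 5 of 52 tested members were higher and 11 lower (5 and 14 adjusted over the list alone). Polycomb-target developmental regulators had a median log2 fold change of -0.17 (camera adjusted p = 0.0267, adjusted p = 0.478 with an estimated correlation), with ISL1 at -0.97 ± 0.14. Fatty acid synthesis, with the elongase gene ELOVL6 at -0.68 ± 0.087 and the carboxylase gene ACACA at -0.38 ± 0.064, passed narrowly: 1 of 16 tested members were higher and 5 lower (2 and 5 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of -0.15 (camera adjusted p = 0.0392, adjusted p = 0.478 with an estimated correlation). That call was lost with length and GC offsets (adjusted p = 0.121, median -0.12), without caged replicate 1 and without 8 h replicate 2. Under cyclic loess offsets the very long neuronal (adjusted p = 0.0609, median -0.10), HOX (adjusted p = 0.176, median -0.094) and Polycomb (adjusted p = 0.274, median -0.064) lists lost their calls.

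Markers of other cell types did not pass camera as lists at 8 h. Some passed with fry, which weighs whether members move, on balance, one way, although their members were split: 5 of 9 epithelial and kidney markers had a positive fold change (fry adjusted p = 0.00553), 5 of 10 fibroblast markers (fry adjusted p = 0.0397) and 4 of 14 neuronal markers (fry adjusted p = 0.0442). Their median log2 fold changes were 0.076, 0.043 and -0.14 and their means -0.13, 0.31 and -0.093, so that for epithelial and kidney markers the median was positive and the mean negative. The counts were 2 higher and 0 lower of 10 (2 and 0 adjusted over the list alone) for fibroblast markers, which hold PDGFRB and ACTA2 (0.62 ± 0.063), and 0 higher and 2 lower of 9 (0 and 1 adjusted over the list alone) for epithelial and kidney markers, of which LRP2 stood at -0.98 ± 0.10. They were 1 higher and 2 lower of 14 (0 and 1 adjusted over the list alone) for neuronal markers and 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone) for blood cell markers. Scarce features were again among the largest called folds. UTP14C had 0 counts in the caged libraries and reached 9.53 ± 0.770 CPM, at least 116-fold higher. TRIM55 stood at 3.04 ± 0.49, ATOH1 at -2.39 ± 0.48 and the ephrin receptor gene EPHA5 at -2.54 ± 0.41. The estimates of UTP14C were not whole in 2 libraries, both at 8 h, and those of EPHA5 in 5, so reads shared with other transcripts leave them uncertain. Of the 59 called genes named for this comparison, 53 kept their call with each library left out in turn. Under glmTreat DNMT1, DNMT3A, DNMT3B, TDG, CDKN1A, RPL24, ACACA, TUG1 and MAGEA3 lost theirs. Without one of the 4 libraries compared the fit called 1373 to 1727 features higher and 902 to 1369 lower, and with library totals alone 29.03% of calls were higher in place of 53.03%, with the median of all features shifted to -0.11.

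**Figure D3:**
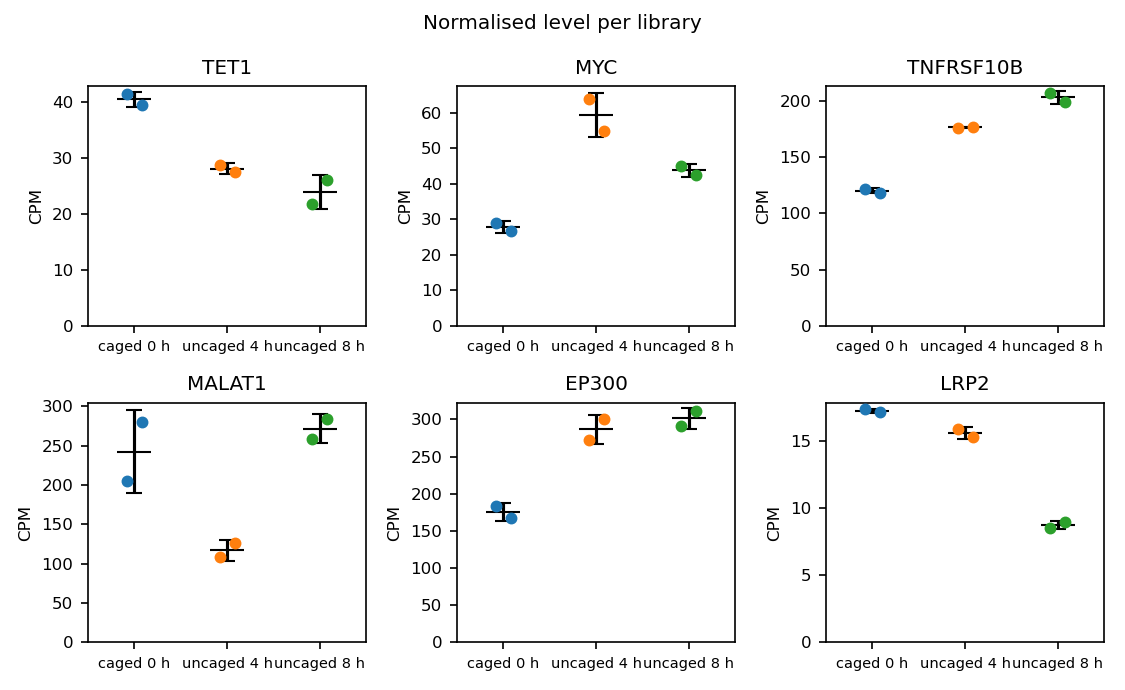
Normalised level in CPM of 6 genes in each library, with a point per library, a dash for the group mean and bars for the SD; the 6 were chosen after their values were seen. TET1 and LRP2 are lowest at 8 h, TNFRSF10B is highest at 8 h, and MALAT1 is lowest at 4 h.

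The changes at 4 h and at 8 h overlapped. Of the features called at 4 h, 895 of 1074 higher ones were also higher at 8 h and 449 of 622 lower ones also lower, while 3 were called in opposite directions. Independent lists of these sizes would share 160 and 82.2 features, and unchanged groups simulated against the same controls shared a mean of 0.8 and 0.4. Those simulated groups had a mean of 4.2 calls at 4 h, so they could not have shared many, and their overlap says nothing of real effects. Across 12425 features over 4 CPM, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.72 against 0.49 simulated, and a covariance of 0.0749 against 0.0111 simulated. Both comparisons use the same 2 caged libraries, too few to split, so part of the excess may come from the shared controls. The 1344 shared calls became 883 with DESeq2, 855 with a replicate block, 173 under glmTreat and 2167 with length and GC offsets.

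**Figure D4:**
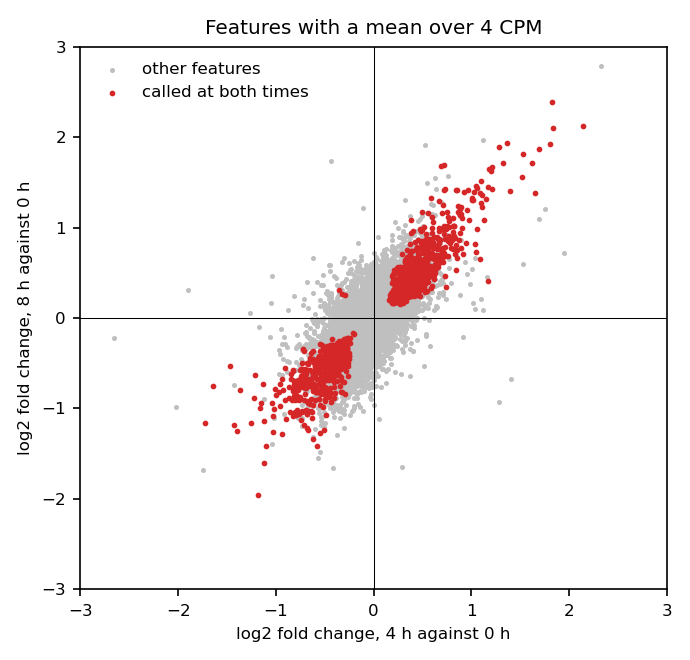
Log2 fold change at 8 h against that at 4 h, both relative to caged cells, for 12425 features with a mean over 4 CPM; axes end at 3 on either side, and red points were called at both times. Most red points lie in the quadrants where both changes have the same sign.

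Between 4 h and 8 h, when every library had received light, washing and fresh medium, fewer features differed. At 8 h 358 were higher and 212 lower, with a median called change of 1.37-fold. Time since light, washing, fresh medium and uncaging advanced together in this step, so their effects cannot be separated here either. MALAT1 (chromosome 11, 65497688 to 65506516) rose from 117 ± 13.4 to 272 ± 18.1 CPM, by 1.21 ± 0.14 (adjusted p = 0.0161), after its fall at 4 h; with robust=TRUE neither change of MALAT1 passed (adjusted p = 0.0533 at 4 h and 0.0586 for this step). The mitotic genes KIF18A and DLGAP5 rose by 1.03 ± 0.17 and 0.86 ± 0.13, and the nucleolar genes NOP58 and NCL by 0.61 ± 0.079 and 0.56 ± 0.062. MYC (-0.44 ± 0.090), SLC7A1 (-0.39 ± 0.056) and the cholesterol regulator gene SREBF2 (-0.30 ± 0.051) fell. These calls rested on few libraries: 1 of the 36 called genes named for this comparison, UTP14C, kept its call with each library left out in turn, and without 4 h replicate 1 the fit called 6 features higher and 0 lower. The calls were 9 and 1 without 4 h replicate 2, 25 and 8 without 8 h replicate 2, 173 and 28 without 8 h replicate 1, 197 and 77 without caged replicate 1, and 196 and 74 without caged replicate 2. Cyclic loess offsets ended the calls of RPL24, SON, MDM2, MT-ND6, MYC, ATP5PB, DDB2 and MT-ATP8 in this step, and length and GC offsets those of MT-ND6, MT-ATP8 and SREBF2. DESeq2 ended those of MAGI2 (adjusted p = 0.0885) and SLC9A9 (adjusted p = 0.0545), robust=TRUE also that of MT-ND6, and library totals alone those of ATP5PB, H2BC12, DDB2 and MT-ATP8. With the 4 compared libraries alone MYC, MAGI2, H2BC12, DDB2 and MT-ATP8 lost their calls. A replicate block ended those of RPL24, KIF18A, PSMB6, MT-ND6, ACACA, MAGI2, SREBF2, EPHA5, ATP5PB, H2BC12, MRPS31, SLC9A9, DDB2, FOXC1, NPIPB2 and MT-ATP8. Without a low-count filter every one of those 36 genes lost its call except RPL6, ZNF195, ZNF430, NOP58, NCL, MALAT1, LRP2, UTP14C, NPIPB14P and RCC2-AS1, and under glmTreat every one except UTP14C, NPIPB14P and RCC2-AS1. With library totals alone 35.4% of calls were higher in place of 62.8%.

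In this step 20 lists passed camera with the preset correlation and 0 with an estimated one, and fry passed 3, against 12 at 4 h and 27 at 8 h. Over the 3 comparisons fry kept 32 of camera's list calls and lost 23. The calls lost under fry are not named list by list in this text. For p53 targets, 5 of 32 tested members were higher and 0 lower (18 and 0 adjusted over the list alone). Targets of p53 had a median log2 fold change of 0.20 (camera adjusted p = 3.03e-10, adjusted p = 0.344 with an estimated correlation), among them GADD45A (0.42 ± 0.062) and MDM2 (0.25 ± 0.043). For splicing factors, 6 of 37 tested members were higher and 0 lower (22 and 0 adjusted over the list alone). Splicing factors had a median log2 fold change of 0.18 (camera adjusted p = 9.25e-11, adjusted p = 0.345 with an estimated correlation), with SRSF11 at 0.47 ± 0.072 and SON at 0.33 ± 0.050. For G2/M genes, 7 of 57 tested members were higher and 0 lower (20 and 2 adjusted over the list alone). G2/M genes had a median log2 fold change of 0.19 (camera adjusted p = 2.54e-09, adjusted p = 0.344 with an estimated correlation). For cytosolic ribosomal proteins, 8 of 80 tested members were higher and 0 lower (33 and 0 adjusted over the list alone). Cytosolic ribosomal proteins had a median log2 fold change of 0.13 (camera adjusted p = 1.14e-14, adjusted p = 0.382 with an estimated correlation), with RPL6 at 0.36 ± 0.040 and RPL24 at 0.27 ± 0.046. The proteasome, with PSMB6 at 0.34 ± 0.062, gave a like result: 4 of 36 tested members were higher and 0 lower (17 and 0 adjusted over the list alone). Proteasome genes had a median log2 fold change of 0.15 (camera adjusted p = 4.69e-09, adjusted p = 0.344 with an estimated correlation). Zinc finger ZNF genes held ZNF195 (0.83 ± 0.10) and ZNF430 (0.77 ± 0.10): 28 of 451 tested members were higher and 3 lower (60 and 8 adjusted over the list alone). ZNF genes had a median log2 fold change of 0.14 (camera adjusted p = 2.34e-05, adjusted p = 0.344 with an estimated correlation). In Myc targets and ribosome biogenesis, 5 of 46 tested members were higher and 1 lower (9 and 1 adjusted over the list alone). Myc and ribosome biogenesis genes had a median log2 fold change of 0.070 (camera adjusted p = 0.0140, adjusted p = 0.344 with an estimated correlation). In the heat shock response, 3 of 27 tested members were higher and 1 lower (8 and 1 adjusted over the list alone). Heat shock genes had a median log2 fold change of 0.11 (camera adjusted p = 0.00286, adjusted p = 0.344 with an estimated correlation), with HSPA4 at 0.52 ± 0.084. Cyclic loess offsets ended the calls of cytosolic ribosomal proteins (adjusted p = 0.799, median 0.018), Myc and ribosome biogenesis genes (adjusted p = 0.362, median 0.039) and heat shock genes (adjusted p = 0.357, median 0.029).

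The 3 mitochondrial lists passed as well, and none of them did with length and GC offsets. Of the mitochondrially encoded genes, 4 of 13 tested members were higher and 0 lower (8 and 0 adjusted over the list alone). Mitochondrially encoded genes had a median log2 fold change of 0.20 (camera adjusted p = 4.80e-05, adjusted p = 0.345 with an estimated correlation). Members included MT-ND6 at 0.59 ± 0.11 and MT-ATP8 at 0.26 ± 0.052. Camera's direction for the list turned, without passing, under length and GC offsets (adjusted p = 0.948) and cyclic loess offsets (adjusted p = 0.605). The list's median shrank but stayed positive under both (0.0258 and 0.0264). For nuclear-encoded oxidative phosphorylation, 4 of 75 tested members were higher and 0 lower (7 and 0 adjusted over the list alone). Oxidative phosphorylation genes had a median log2 fold change of 0.089 (camera adjusted p = 2.07e-05, adjusted p = 0.498 with an estimated correlation), with ATP5PB at 0.25 ± 0.048, and with length and GC offsets the call was lost (adjusted p = 0.151, median 0.022). For mitochondrial ribosomal proteins, 1 of 78 tested members were higher and 0 lower (0 and 0 adjusted over the list alone). Mitochondrial ribosomal proteins had a median log2 fold change of 0.10 (camera adjusted p = 1.72e-05, adjusted p = 0.345 with an estimated correlation), and MRPS31 rose by 0.46 ± 0.088. Its call too was lost with length and GC offsets (adjusted p = 0.0711, median 0.051). Nuclear-retained noncoding RNAs (1 higher and 0 lower of 24 (3 and 0 adjusted over the list alone); camera adjusted p = 0.00223, adjusted p = 0.344 with an estimated correlation) held MALAT1. Core polyadenylated histone genes held H2BC12 (0.48 ± 0.10): 1 of 12 tested members were higher and 0 lower (2 and 0 adjusted over the list alone). Core polyadenylated histone genes had a median log2 fold change of 0.37 (camera adjusted p = 0.00103, adjusted p = 0.344 with an estimated correlation). Nucleotide excision repair and UV damage held DDB2 (0.26 ± 0.055): 1 of 26 tested members were higher and 0 lower (2 and 0 adjusted over the list alone). These repair genes had a median log2 fold change of 0.092 (camera adjusted p = 0.0419, adjusted p = 0.344 with an estimated correlation). The repair list lost its call under cyclic loess offsets (adjusted p = 0.194, median 0.045), without either 4 h library, without 8 h replicate 1 and with camera on ranks.

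Of the lists that passed, 6 stood lower at 8 h than at 4 h. In fatty acid synthesis, 0 of 16 tested members were higher and 1 lower (0 and 7 adjusted over the list alone). Fatty acid synthesis genes had a median log2 fold change of -0.16 (camera adjusted p = 4.80e-05, adjusted p = 0.344 with an estimated correlation), with ACACA at -0.37 ± 0.064. In cholesterol biosynthesis, 0 of 26 tested members were higher and 1 lower (0 and 1 adjusted over the list alone). Cholesterol biosynthesis genes had a median log2 fold change of -0.11 (camera adjusted p = 0.0140, adjusted p = 0.345 with an estimated correlation). Among very long neuronal genes, 0 of 24 tested members were higher and 2 lower (0 and 6 adjusted over the list alone). Very long neuronal genes had a median log2 fold change of -0.22 (camera adjusted p = 0.000424, adjusted p = 0.345 with an estimated correlation), with AUTS2 at -0.57 ± 0.10 and MAGI2 at -0.91 ± 0.17. Neuronal markers did not pass (0 higher and 0 lower of 14 (0 and 0 adjusted over the list alone); camera adjusted p = 0.703). Among solute carriers, 0 of 254 tested members were higher and 8 lower (0 and 8 adjusted over the list alone). Solute carriers had a median log2 fold change of -0.10 (camera adjusted p = 0.000248, adjusted p = 0.344 with an estimated correlation), with SLC9A9 at -0.68 ± 0.11. HOX genes passed with no called member: 0 of 37 tested members were higher and 0 lower (0 and 0 adjusted over the list alone). HOX genes had a median log2 fold change of -0.12 (camera adjusted p = 0.0232, adjusted p = 0.537 with an estimated correlation). Wnt targets, of which MYC was the called member, gave a like result: 0 of 19 tested members were higher and 1 lower (0 and 1 adjusted over the list alone). Wnt targets had a median log2 fold change of -0.17 (camera adjusted p = 0.0199, adjusted p = 0.382 with an estimated correlation). The Wnt call was lost with length and GC offsets (adjusted p = 0.148, median -0.11), cyclic loess offsets (adjusted p = 0.0951, median -0.13), without 4 h replicate 2 and without 8 h replicate 1. That of HOX genes was lost under cyclic loess offsets (adjusted p = 0.197, median -0.079), without 4 h replicate 2 and without 8 h replicate 2, and that of cholesterol biosynthesis without 4 h replicate 1. LRP2 stood at -0.84 ± 0.10, EPHA5 at -2.32 ± 0.42 and FOXC1 at -0.38 ± 0.060. UTP14C had 0 counts at 4 h as in caged cells and was at least 96.3-fold higher at 8 h, with the uncertainty of shared reads given above.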

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

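The test of mCherry transcript for p53 targets, the test of nuclear RNA and the test of shared estimates were chosen after the results were seen, and so was the reading of the offset tests as bearing on the whole cause. All of the values in this part were noticed in the data they were tested on, so each explanation is a hypothesis. Intervals of list medians come from resampling the list's members, which share the same libraries, so they leave out the spread between libraries. The interval of a share of features also treats the features as independent.

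A change from 0 h to 4 h that was followed by a called change in the opposite direction from 4 h to 8 h appeared in 45 features that were lower and then higher and 24 that were higher and then lower. Both steps use the same 4 h libraries, so an error in those libraries moves the steps in opposite directions. Among genes picked by the naming rule, MALAT1 changed by -1.05 and then 1.21, MT-ND6 by -0.78 and then 0.59, MT-ATP8 by -0.31 and then 0.26, NPIPB14P by -1.90 and then 2.21, and NPIPB2 by -1.05 and then 1.29 (log2). MYC changed by 1.09 and then -0.44, SLC7A1 by 0.57 and then -0.39, ZNF503 by 0.74 and then -0.40, FOXC1 by 0.53 and then -0.38, and SREBF2 by 0.30 and then -0.30. The antisense RNA RCC2-AS1 had 0 counts in both 4 h libraries and was at least 44.7-fold higher at 8 h against 3 counts over the group; its fitted log2 value of 9.14 depends on the prior count. Each of these second steps lost its call without either 4 h library.

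For the 45 features that were lower at 4 h and higher again at 8 h, a lower share of nuclear RNA in the 4 h libraries was weighed first. The other 23 listed nuclear-retained noncoding RNAs had a median log2 fold change of 0.0414 at 4 h (95% interval -0.016 to 0.101). Of these 23, 8 stood lower, and the nuclear RNA KCNQ1OT1 was called lower at 4 h. The median argues against a loss across the listed RNAs as a class and leaves a loss of single nuclear RNAs open. How far each listed RNA is nuclear was not tested. With length and GC offsets, 38 of the 45 (84.4%, interval 70.5% to 93.5%) were still called in both steps, which argues against such a trend as the whole cause, although MT-ND6 and MT-ATP8 lost their second call with these offsets and under cyclic loess. The interval reaches below the bound set for it beforehand, so a part of the pattern, those 2 genes included, may come from it. A response of these genes to activation stays open and was not tested apart from light and medium.

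The p53 targets stood higher at 8 h by a median of 0.40, and with length and GC offsets by 0.431 (interval 0.345 to 0.50) with 25 of 32 members called higher, which argues against that trend as the whole cause. Under cyclic loess offsets the median was 0.259 (interval 0.161 to 0.318) with 19 members called, which argues against a trend with abundance as the whole cause and leaves open that it may account for a part. The list was higher at 8 h than at 4 h by a median of 0.20 (interval 0.111 to 0.231), with 30 of 32 members higher, while the mCherry (-0.24 ± 0.049) and CMV (-0.23 ± 0.047) sequences were lower (adjusted p = 0.0431 and 0.0437). The amber segment (0.18 ± 0.041), the start segment (0.063 ± 0.022) and the remaining plasmid sequence (0.067 ± 0.041) did not pass in that step (adjusted p = 0.0549, 0.135 and 0.370), so the plasmid sequences move apart and transcript from the TET2 segments stays open. Light without the enzyme stays open because no group received it alone.

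Called changes of over 4-fold in any comparison, 132 features, were weighed against estimates divided among transcripts that share sequence. Estimates were not whole in at least 4 libraries for 51.5% of them and 51.5% of the other tested features (Fisher's exact test, p = 1). An estimate of 0 counts as whole, so features at 0 in several libraries, as some large folds are, can hardly reach 4. The equal shares under this definition therefore do not argue against the explanation. Counting features with an estimate that was not whole in any library, the definition looked at before the stricter one was adopted, gave 77.3% against 66.5% (Fisher's exact test, p = 0.00925). For the 25 such features of the step from 4 h to 8 h both definitions were above the other features, with 72% against 51.5% (p = 0.0455) and 100% against 66.6% (p = 5.43e-05, Fisher's exact tests, not adjusted over the 3 comparisons). Over all comparisons the 2 definitions part ways, so the explanation cannot be told apart from a change in transcript level.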

How the results depend on the processing

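Plasmid inclusion, length and GC offsets, cyclic loess offsets and the fit of whole estimates were chosen after the data were seen. RLE and upper-quartile factors, limma-voom, the CPM filter, unrounded counts and plasmid inclusion moved no count of calls by over 1.5 times. Main counts were 1074 higher and 622 lower at 4 h, 2602 and 2305 at 8 h, 358 and 212 between them, and 1344 shared. Where a cause is not named, the cause was not tested.

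With library totals alone the counts were 1595 and 3899 at 8 h, and 447 were lower between 4 h and 8 h. DESeq2 gave 257 lower at 4 h, 1116 lower at 8 h and 883 shared. Without a low-count filter there were 447 and 264 at 4 h, 1597 higher at 8 h, 48 and 5 between, and 583 shared. glmTreat, which asks for over 1.2-fold, gave 155 and 62, 788 and 619, 9 and 0, and 173 shared; the 0 stands beside 4032 features of either direction at an unadjusted p under 0.05 and 148 lower by DESeq2. robust=TRUE gave 631 and 420 between 4 h and 8 h, and the 4 libraries alone 137 lower. Length and GC offsets gave 1668 and 975 at 4 h, 759 and 355 between, and 2167 shared. Cyclic loess gave 888 shared and reversed 8 calls at 8 h, the only main calls that any setting reversed. Whole estimates alone left 5826 features, which limits the counts by construction: 443 higher at 4 h, 879 and 1237 at 8 h, 211 higher between, and 678 shared.

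With a replicate block there were 709 and 330 at 4 h, 151 and 42 between, and 855 shared; TET2 between 4 h and 8 h stood at 0.157 and lost its call. Deviations of same-numbered libraries correlated at 0.00081, 0.047 and -0.050 across all tested features, and at -0.18, 0.24 and -0.35 over 8 CPM. The signs differ between groups of 2 libraries, so a shared day or batch behind the replicate numbers is neither shown nor excluded.

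The TET2 rise was 0.313 under glmTreat and 0.0997 under cyclic loess at 4 h, and 0.0744 under cyclic loess at 8 h, without a call. Its step from 4 h to 8 h lost its call with library totals (0.104), no filter (0.157), the 4 libraries alone (0.158), legacy=FALSE (0.158), robust=TRUE (0.158) and glmTreat (0.158), and turned to -0.0253 under cyclic loess; none of the 6 fits without 1 library called it (adjusted p = 0.0648 to 0.174). With an estimated correlation 0, 0 and 0 lists passed; cyclic loess left 9 at 4 h and fry 3 between 4 h and 8 h. Under cyclic loess camera's direction turned for the proteasome at 4 h (adjusted p = 0.867) and ATF4 targets at 8 h (0.488). It also turned for cytosolic ribosomal proteins at 8 h (5.98e-10). For mitochondrially encoded genes from 4 h to 8 h it turned under length and GC offsets (0.948) and cyclic loess (0.605). The median of these mitochondrial genes stayed positive under both (0.0258 and 0.0264). Of the other list values, 685 held and 135 lost the call; of the named-gene values, 2971 held, 372 lost and 1 gained a call.

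Leaving out 1 library gave 165 to 943 higher and 61 to 672 lower at 4 h, 1373 to 2246 and 902 to 2082 at 8 h, 6 to 197 and 0 to 77 between, and 195 to 1069 shared. Calls kept in all 6 such fits were 143 and 31, 1073 and 664, and 5 and 0. TET2 ranged from 0.304 to 0.321 at 4 h, 0.424 to 0.507 at 8 h and 0.119 to 0.202 between. Lists that passed numbered 11 to 16, 15 to 22 and 17 to 21. Depth limits the low features: 3 counts are 0.164 to 0.210 CPM in a library.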

Other observations

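Several gene groups passed camera in none of the comparisons and are given here with their counts at 8 h. Of these, fry passed YAP targets (adjusted p = 0.00461 at 4 h and 0.00172 at 8 h), apoptosis regulators (0.0163 and 0.00553) and growth arrest genes (0.0493 at 8 h). The medians of these lists at 8 h were 0.0093, -0.0065 and 0.080. Stress lists stood at 4 higher and 3 lower of 27 (4 and 3 adjusted over the list alone) for NRF2 targets, 7 higher and 4 lower of 30 (7 and 4 adjusted over the list alone) for the unfolded protein response, 3 higher and 10 lower of 31 (4 and 10 adjusted over the list alone) for hypoxia and 1 higher and 0 lower of 5 (1 and 0 adjusted over the list alone) for metallothioneins. Signalling lists stood at 1 higher and 5 lower of 24 (1 and 5 adjusted over the list alone) for interferon-stimulated genes, where IFIT5 was at -0.77 ± 0.14, 3 higher and 3 lower of 20 (3 and 3 adjusted over the list alone) for NF-kB targets, 3 higher and 4 lower of 18 (3 and 4 adjusted over the list alone) for Notch targets, 6 higher and 4 lower of 21 (8 and 6 adjusted over the list alone) for YAP targets and 2 higher and 4 lower of 16 (2 and 4 adjusted over the list alone) for glucocorticoid targets. The circadian clock had 3 higher and 5 lower of 18 (3 and 5 adjusted over the list alone), with PER2 at 0.83 ± 0.10. Metabolic lists had 3 higher and 1 lower of 20 (3 and 1 adjusted over the list alone) for glycolysis and 5 higher and 2 lower of 29 (1 and 2 adjusted over the list alone) for the tricarboxylic acid cycle.

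Lists close to DNA methylation gave 4 higher and 3 lower of 23 (5 and 8 adjusted over the list alone) for base excision repair, 5 higher and 3 lower of 19 (5 and 3 adjusted over the list alone) for imprinted genes, 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone) for pluripotency factors and 2 higher and 1 lower of 13 (2 and 1 adjusted over the list alone) for germline and cancer-testis genes, of which MAGEA3 stood at 0.47 ± 0.10 and PRAME at -0.46 ± 0.074. Apoptosis regulators had 6 higher and 2 lower of 26 (6 and 2 adjusted over the list alone), growth arrest genes 4 higher and 2 lower of 11 (4 and 2 adjusted over the list alone), and antisense and intergenic noncoding RNAs 60 higher and 41 lower of 742 (28 and 16 adjusted over the list alone). Clustered protocadherins (4 tested members, 0 called) and olfactory receptors (2 tested, 0 called) were too few for a list test.

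The test of exon number and the test of abundance, in the form given, were chosen after the results were seen, and so was the reading of the stop codon test. If genomic DNA gave a dependence on exon number, silent olfactory receptor genes would rise. Silent genes give no unspliced transcripts, so this test does not bear on unspliced reads, which were not tested. The summed counts of these receptor genes, 783 over 4 libraries, changed by 0.128 (log2, interval -0.079 to 0.334) at 8 h. The interval, which covers counting error only, lies below the rise of 0.5 written for this beforehand and reaches above the 0.2 written against it, so it does not decide. A rise of few-exon genes as a group may be part of the response: across 11528 protein-coding genes, which are not independent replicates, the partial Spearman correlation of exon number and fold change at 8 h was -0.0664 (interval -0.085 to -0.048), between the bounds set for and against. Readthrough of amber stop codons could have moved genes that end in TAG: they differed from TAA and TGA genes by a median of -0.00394 at 8 h (interval -0.023 to 0.014) and 0.0144 at 4 h (interval 0.0022 to 0.024). Beforehand a difference of at least 0.05 in one direction at both times was asked for. All 6 libraries had the caged amino acid for 48 h, so an effect common to all of them would cancel in these fold changes. Readthrough itself was not measured. The medians argue against a difference of that size from caged cells at 4 h and 8 h, and a smaller one is not excluded. Their intervals come from resampling genes and leave out the spread between libraries.

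Fold change at 8 h rose with abundance across features, which are not independent replicates. Over the 12425 features above 4 CPM the Spearman correlation was 0.358, and 0.360 (interval 0.345 to 0.375) with length and GC offsets, which argues against those trends as its source. The test was first run on all 17449 features, where the correlation was 0.122 without and 0.144 with offsets, and moved to the more abundant features after that value was seen; the bound of 0.2 written for it is met only in the second form.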
